A study of Homo sapiens with 6 samples.

How the data were processed

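Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for FOXA1, a forkhead transcription factor, in LNCaP, an established prostate cancer cell line. Per the labels, stable LNCaP lines carried a tetracycline-inducible, V5-tagged FOXA1, either wild type (WT) or with the forkhead domain change D226G or M253K. Per the labels, cells were kept in medium with 10% tetracycline-free serum and treated with doxycycline for 2 days in medium with 5% CSS, and libraries were made with a ThruPLEX kit. Whether the antibody recognised FOXA1 or the V5 tag, and so whether FOXA1 from the cell's own gene was also captured, is not given in the sources used here.

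Per the submitters' processing notes, the tools were BWA 0.7.2-r351, SAMtools 0.1.18 and MACS2 2.0.10.20131216, and the genome build was hg19 (GRCh37). The notes give neither settings nor filters, and the use of an input control is not given in the sources used here. Per the labels, the 6 samples were 2 technical replicates in each of 3 groups, and the same peak list is named for both replicates of a group. Whether a list was made from both libraries or from 1 of them is not given in the sources used here. Each group thus had 1 list, no spread between replicates could be computed, and every comparison of lists is one of 3 single lists.

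The deposited lists were in the narrowPeak layout of the peak caller. The score column was deposited as a whole-number display score and was not used. The deposited fold enrichment is a ratio of the reads at the summit to a local background. The deposited −log10 p and −log10 q values are the caller's own significance of that enrichment. Fold enrichment and −log10 q are the authors' values for a single peak and were ranked and tested only within one list; their medians or lowest values are given for each list as a description. Fold enrichment and −log10 p also served to work back reads, which were compared between lists. In the authors' deposited table of each group the lowest −log10 q was 1.30 in the WT, 1.34 in the M253K and 1.34 in the D226G list.

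Depth was worked back from the lists. For each peak, the whole number of reads at the summit (the pileup) and the background were found that together give its fold enrichment, with a pseudocount of 1, and its Poisson −log10 p. In simulated peaks (1853, 1826 and 1940, with the fragment lengths of the 3 lists) 100% of pileups and backgrounds were recovered. Their pileups were drawn evenly over a wide range, not as in the lists, and with the same formula. This checks the working back and not whether the formula describes the lists. On the real lists the largest misfit of −log10 p was 0.000107. The backgrounds were whole reads per 10 kb or 1 lowest value for 108815 of the 108816 WT peaks, 46437 of 46437 M253K peaks and 1363 of 1363 D226G peaks (tolerance 0.02 reads). The reads per 10 kb were below the pileup of the same peak in 0 peaks of each list, the form of a background taken from the ChIP library itself. The lowest background, a genome of 2.7 Gb (assumed, as the caller's preset) and the fragment length, taken as the lowest peak width of 145, 134 and 245 bp, gave about 8.70 M (mega) reads for WT and 3.63 M reads for M253K. For D226G the lowest background was itself a whole number of reads, so its value of about 1.35 M reads could be lower. A second, rougher estimate from the reads around D226G and M253K peaks of a pileup of 10 to 15 was 1.36 M reads. These are estimates from the lists, and totals counted from reads were not used here. The highest pileups reached 98.6%, 97.4% and 68.6% of 2 fragment lengths, the most that 1 read per position and strand allows, so the strongest WT and M253K sites may be understated.

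Overlap meant at least 1 shared bp. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only, and peaks are not replicates. Each overlap was set beside 100 random circular shifts of the other list along each chromosome. Each list was split in 10 equal parts (deciles) by fold enrichment. Peaks with and without an overlap were compared within one list by a two-sided permutation test of ranks with 100000 resamples, and their positions by two-sided Fisher's exact tests, each family of 12 adjusted by Benjamini-Hochberg. The named sites were the 5 with the highest fold enrichment in each of 6 classes, a rule fixed before the data were examined, as were the overlaps, the deciles of WT peaks, the chromosome shares and the rank tests within the mutant lists. The chromosome bands, the Fisher tests of position, the correlations of pileups, the deciles of the mutant lists, the rank tests within the WT list and those by M253K overlap, the D226G shares at equal pileup and the splitting of WT reads (100 draws) were chosen after the data were seen. Chromosome bands and lengths of hg19 came from circlize 0.4.16, whose lengths matched hg19 for 24 of 24 chromosomes. Bands under 2 Mb, centromeric bands and variable heterochromatin were left out of the ranking by density. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. The overlap function was checked against bedtools on simulated intervals.

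Alternatives were −log10 q of at least 5 or 10, fold enrichment of at least 5, reciprocal overlap of 50%, summits within 100 bp, a WT list of the size of the M253K list and a ranking by −log10 q. Leaving out centromeric bands and contigs, ranking by pileup, and the list of equal size in the other direction were added after the data were seen. Genes near peaks, genomic annotation and the forkhead motif, all planned, were not analysed here, since no annotation or sequence of hg19 was used here and the gene table at hand is of GRCh38. The FOXA1 gene itself was for the same reason not described. Coordinates are hg19, counted from 1.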

Results

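FOXA1 binding was mapped by ChIP-seq in LNCaP cells that expressed WT FOXA1 or the forkhead domain mutants M253K or D226G after 2 days of doxycycline. Each of the 3 groups had 2 technical replicates, with 1 peak list named for both. Whether a list was made from both libraries or from 1 is not given in the sources used here. The libraries differed in depth, at about 8.70 M reads for WT, 3.63 M for M253K and about 1.35 M or fewer for D226G, as worked back from the lists. By these values WT had about 2.40 times the reads of M253K. Against D226G the factor was 6.45 at 1.35 M reads, and it is larger if D226G had fewer. No value below has a replicate error.

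The WT list held 108816 peaks over 28.2 Mb, the M253K list 46437 peaks over 9.48 Mb, and the D226G list 1363 peaks over 0.420 Mb. They covered 0.910%, 0.306% and 0.0136% of hg19. The median peak was 232 bp wide for WT, 186 bp for M253K and 259 bp for D226G. The lowest width of its list, taken above as the fragment length, was held by 12.4% of WT, 22.6% of M253K and 40.9% of D226G peaks. That lowest width was largest for D226G, so the medians do not rank the breadth of binding. The median fold enrichment within each list was 6.47, 6.24 and 6.43, and the median pileup was 11, 7 and 7 reads. Since the number of peaks called rises with depth, the counts by themselves do not rank the binding of the 3 proteins.

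The 3 lists differed in where along the chromosomes their peaks lay. In the WT list 46.9% of peaks (95% interval 46.6 to 47.2) fell in light-staining bands, the gene-rich part of the chromosomes, which hold 42.2% of hg19. The M253K share was 41.8% (41.4 to 42.3) and the D226G share 42.8% (40.1 to 45.5). The darkest bands, which make up 16.1% of hg19 and are gene-poor, held 15.2% of WT peaks (14.99 to 15.42), 20.6% of M253K peaks (20.2 to 20.9) and 18.3% of D226G peaks (16.3 to 20.5). Centromeric bands and variable heterochromatin, 8.29% of hg19, held 1.66% of WT peaks (1.59 to 1.74), 2.25% of M253K peaks (2.11 to 2.39) and 5.18% of D226G peaks (4.05 to 6.51). Chromosome Y stood lowest in WT, at 0.381 times its length share, and in M253K, at 0.488, and held 0.430 (0.215 to 0.767) in D226G. Chromosome X also held fewer peaks than its length share in every list, at 0.575 times that share for WT, 0.650 for M253K and 0.329 for D226G. Chromosome 22 held 0.612 and chromosome 19 held 0.619 times their length share in WT. Chromosome 5 was above its share in WT (1.20) and M253K (1.23). Chromosome 10 stood highest in D226G, at 1.63 (1.33 to 1.97), against 1.14 in WT and 1.16 in M253K. Intervals cover counting error only, and copy number of these cells, which alters reads per chromosome, was not analysed here. Length shares used full hg19 lengths, and sequence where no peak can be called was not taken out. Low ratios, as for chromosome Y, chromosome 22 and centromeric bands, may in part reflect such sequence.

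**Figure D1:**
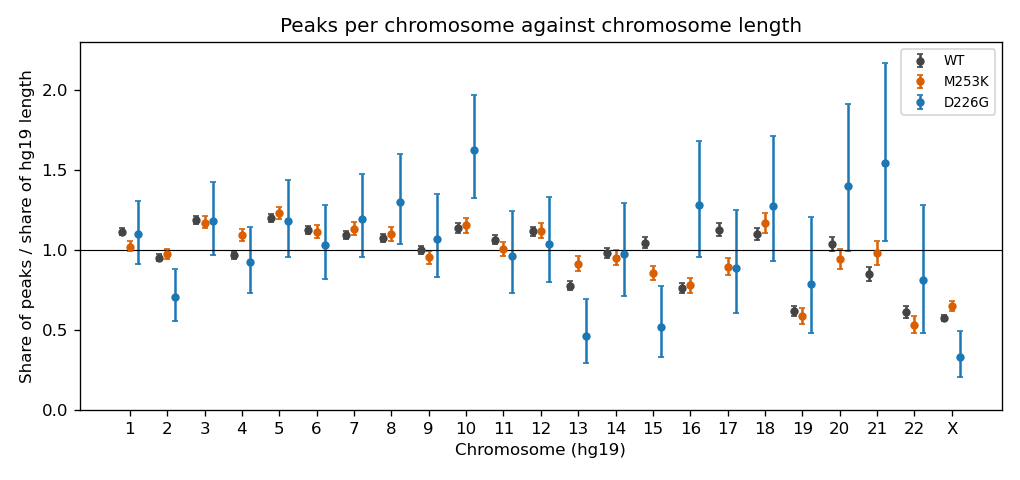
Share of peaks on each chromosome divided by the chromosome's share of hg19 length, for the WT, M253K and D226G lists, with exact 95% intervals of counting error; the line marks a share equal to length. Chromosome X lies below the line in each list, and chromosome 10 reaches 1.63 in D226G.

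The band 5q13.2 was the densest of the WT list, with 88.2 peaks per Mb, and the second of the M253K list, with 33.1 per Mb. 1q31.1 led the M253K list with 36.2 peaks per Mb and held 48.6 per Mb in WT. 10q21.2 followed 5q13.2 in WT, with 74.2 per Mb. In the D226G list 10q11.21 led with 4.21 peaks per Mb (16 peaks), ahead of 9q13 with 3.57 per Mb (10 peaks) and 16p11.2 with 2.31 per Mb (15 peaks). The 16 peaks of 10q11.21 are among the 95 D226G peaks of chromosome 10. Sequence present in several copies, which may add peaks in such bands, was not taken out or tested.

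The comparison of WT with M253K asked which peaks of the WT list were also called in cells with the M253K protein. FOXA1 from the cell's own gene may add peaks to every list, since the target of the antibody is not given in the sources used here. M253K peaks overlapped 19911 of the 108816 WT peaks, 18.3% (18.1 to 18.5), and WT peaks overlapped 20012 of the 46437 M253K peaks, 43.1% (42.6 to 43.5). Shifted lists gave 0.714% and 1.65% on average, so the overlaps on chromosomes were 25.6 and 26.0 times larger, and 0 of 100 shifts gave as many. The remaining 26425 M253K peaks, 56.9% of that list (56.5 to 57.4), had no WT peak. Their median pileup was 7 reads, against 9 for M253K peaks with a WT peak. Outside centromeric bands and contigs the share of M253K peaks without a WT peak was 46.8% at a pileup of at least 10, 24.3% at 30 and 9.63% (107 of 1111 peaks) at 60. Limited to its 46437 strongest peaks by −log10 q, the WT list was overlapped at 27.5%, and it overlapped 27.9% of M253K peaks.

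Overlap was highest for the strongest peaks. In the weakest decile of WT peaks 1110 of 10882 (9.64% to 10.8%) were overlapped by M253K peaks, and in the strongest 4802 of 10881, 44.1% (43.2 to 45.1). WT overlap of M253K peaks did not rise steadily with fold enrichment. It was 36.1% (34.7 to 37.5) in the weakest decile, 32.0% (30.6 to 33.3) in the third, and between 40.1% and 46.1% from there to the ninth. In the strongest it was 69.1% (67.7 to 70.4). Ranked by pileup, a ranking chosen after the data were seen, it rose from 30.8% in the weakest decile to 48.5% in the ninth and 73.2% in the strongest, with 1 step down, from 45.6% to 44.3%, at the eighth. WT peaks with an M253K overlap had a median fold enrichment of 8.35 against 6.13 without and were the stronger in 67.0% of pairs. M253K peaks with a WT overlap had a median of 6.75 against 5.93 (stronger in 58.6% of pairs) and a median width of 209 bp against 170 bp. Each of these within-list permutation tests gave p = 1e-05, the smallest that the resamples can give, and an adjusted p of 1e-05 over 12 tests, comparing peaks of one list.

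**Figure D2:**
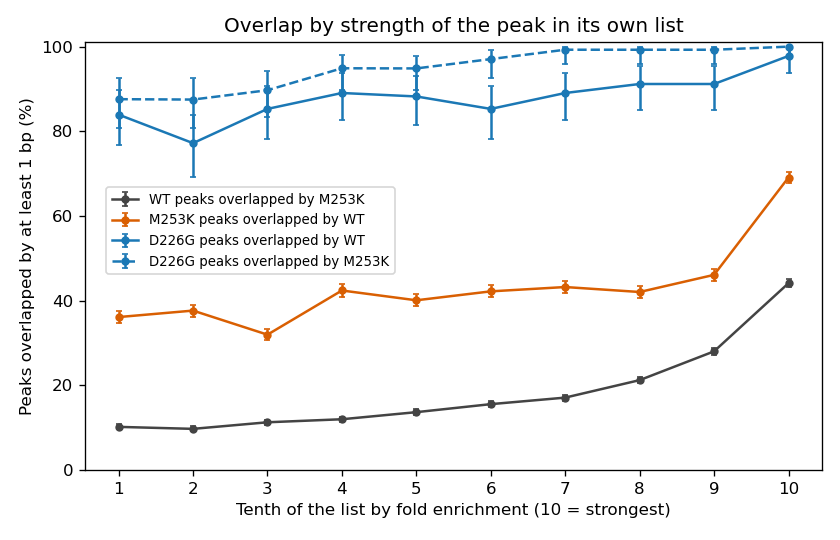
Percent of peaks overlapped by another list, by decile of fold enrichment within the peak's own list, with exact 95% intervals of counting error. WT peaks overlapped by M253K reach 44.1% in the strongest decile, and D226G peaks overlapped by WT reach 97.8%.

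M253K peaks with and without a WT peak also differed in position. Of those without, 21.8% (21.3 to 22.3) lay in the darkest bands, against 18.9% (18.4 to 19.5) of those with one (Fisher's exact test, adjusted p = 3.79e-14). On chromosome X the shares were 3.92% and 2.38% (Fisher's exact test, adjusted p = 3.9e-20). WT peaks without an M253K peak also lay there more often than those with one, at 2.998% against 2.37% (Fisher's exact test, adjusted p = 2.42e-06). A higher share on chromosome X was thus found for the unshared peaks of both lists and was not particular to M253K. WT peaks with an M253K peak lay in the darkest bands more often than those without, at 18.8% against 14.4% (Fisher's exact test, adjusted p = 6.52e-52). The whole M253K list held more of its peaks there than the WT list, 20.6% against 15.2%. Both differences for the darkest bands may follow from that alone. Fisher's tests count neighbouring peaks as independent, so these p-values measure no spread between libraries.

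Single sites spanned these classes. Reads at a site are given as worked back, not scaled to depth, so they do not rank the 3 proteins there. At 1059 sites called in all 3 lists, the median M253K to WT pileup ratio per estimated read was 3.18 (quartiles 1.22 to 7.70). These sites lay outside centromeric bands and contigs, and each M253K peak was counted once. Requiring a D226G peak may select sites that are high in M253K, so the ratio need not hold for other shared sites. The WT peak of highest fold enrichment, at 3q29 (chromosome 3, 196625562 to 196625863), had 132 reads at its summit and a peak in both mutant lists, with 144 reads for M253K and 82 for D226G. At 17p13.2 (chromosome 17, 5135485 to 5135900) WT had 143 reads, M253K 17 and D226G 12. At 17q24.3 (chromosome 17, 69568915 to 69569335) WT had 102, M253K 148 and D226G 15 reads. A pair of sites at 16p11.2 (chromosome 16, 32236245 to 32236639 and 32715412 to 32715834) had 159 and 165 reads in WT, 156 and 151 in M253K, and 10 and 7 in D226G. Their near-equal heights in WT and in M253K leave open whether they share sequence. M253K but not D226G overlapped 18752 WT peaks, and the 5 of highest fold enrichment were led by 18q22.3 (chromosome 18, 70856959 to 70857360; 143 WT and 27 M253K reads). Among these 5 the weakest M253K peak was at 12q14.2 (chromosome 12, 64199764 to 64200171), with 103 WT and 6 M253K reads.

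The strongest WT peaks with no mutant overlap lay at 6q21 (chromosome 6, 106284087 to 106284532; fold enrichment 30.3, 90 reads), 11q24.1, 17q23.3, 8q24.3 and 3q21.1, with 65 to 108 reads. The strongest M253K peaks with no WT overlap lay at 2p12 (chromosome 2, 76444535 to 76444802; fold enrichment 39.4, 108 reads), 3p11.1, 2q34, 14q23.1 and 11p14.1, with 79 to 126 reads. Of these, the sites at 3p11.1 and 2q34 also had a D226G peak, with 5 and 7 reads.

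At sites called in both lists, the heights of WT and M253K peaks were only loosely related. Over 19911 overlapping pairs the Spearman correlation of pileups was 0.102, and 0.0767 outside centromeric bands and contigs. When WT reads at the latter sites were split at random into parts with no read in common, 1 of them at the M253K depth, the parts correlated at 0.747 on average, the level that counting noise alone leaves. How far replicate libraries would agree is not known. These are correlations across sites of 1 library each, and sites are not independent replicates. Summits lay a median of 37 bp apart, and 83.9% lay within 100 bp.

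The comparison of WT with D226G asked the same of the other mutant. D226G peaks overlapped 1204 WT peaks, 1.11% (1.05 to 1.17), and WT peaks overlapped 1197 of the 1363 D226G peaks, 87.8% (86.0 to 89.5). That was 42.1 times the mean of shifted lists (2.09%), and 0 of 100 shifts gave as many. D226G peaks with a WT overlap had a median fold enrichment of 6.55 against 6.04 without (stronger in 61.6% of pairs, permutation p = 1e-05, the smallest the resamples can give). Among WT peaks with a pileup of 60 to 99 outside centromeric bands and contigs, 148 of 917 had a D226G peak, 16.1% (13.8 to 18.7).

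M253K peaks overlapped 1294 of the 1363 D226G peaks, 94.9% (93.6 to 96.0), 122 times the mean of shifted lists (0.777%). In the strongest decile of D226G peaks, 136 of 136 had an M253K peak and 133 had a WT peak. Merging all lists gave 135132 regions. Of the regions with a D226G peak, 1148 were in all 3 lists, 142 in M253K and D226G only, 44 in WT and D226G only, and 19 in D226G alone. The Spearman correlation of D226G pileups was 0.549 with those of M253K over 1294 pairs and 0.340 with those of WT over 1197 pairs. On the 1055 D226G peaks in all 3 lists outside centromeric bands and contigs, the correlations were 0.532 and 0.269. The difference between them was not tested, and sites are not replicates.

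At 10p12.31 (chromosome 10, 22589096 to 22589671) D226G had 90 reads and M253K 111, while WT had 10, again not scaled to depth. At 8q24.22 (chromosome 8, 133945338 to 133945778) the reads were 37 for D226G, 208 for M253K and 108 for WT. The 5 strongest D226G sites with no WT peak, at 3q26.1, 9q21.31, 7q21.13, 21q21.2 and 11q22.1, had 12 to 16 D226G reads. Each had an M253K peak, with 20 reads at 3q26.1 (chromosome 3, 165990458 to 165990846) and 85 at 9q21.31 (chromosome 9, 83608430 to 83608730).

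WT peaks of equal height were called in D226G mainly where M253K had a peak. Among WT peaks with a pileup of 60 to 99 outside centromeric bands and contigs, D226G peaks overlapped 147 of the 680 with an M253K peak, 21.6% (18.6 to 24.9), and 1 of the 237 without, 0.422% (0.0107 to 2.33). At pileups of 30 to 59 the shares were 9.85% (8.88 to 10.9) of 3481 and 0.470% (0.279 to 0.742) of 3830. M253K peaks of equal height were in turn called in D226G more often where WT had a peak. At M253K pileups of 30 to 59 D226G peaks overlapped 12.7% (11.2 to 14.4) of the 1735 with a WT peak and 5.84% (4.29 to 7.73) of the 771 without. At M253K pileups of 60 to 99 the shares were 31.2% (27.8 to 34.8) and 20.2% (12.6 to 29.8), with intervals that meet. From 100 on they were 65.1% (59.5 to 70.3) of 312 and 7.69% (0.195 to 36.0) of 13. These ranges of pileup were chosen after the data were seen.

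**Figure D3:**
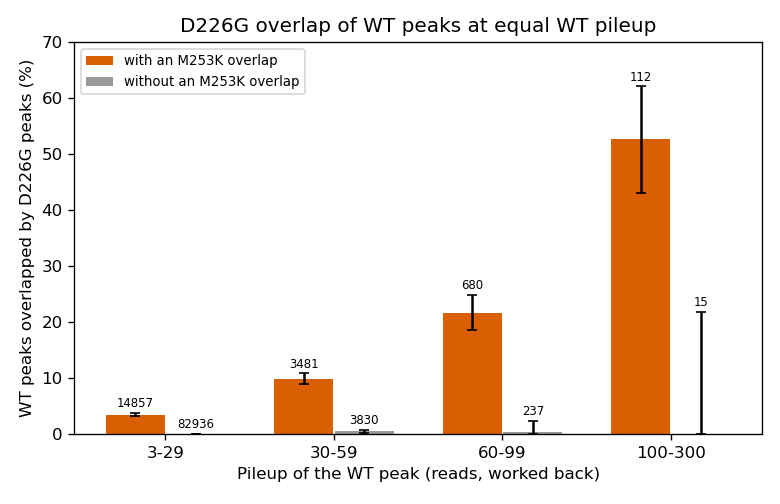
Percent of WT peaks overlapped by D226G peaks, by pileup of the WT peak in reads, with and without an M253K overlap; error bars are exact 95% intervals of counting error and the number over each bar counts WT peaks. At a pileup of 60 to 99 the shares are 21.6% and 0.422%.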

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

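No paired analysis was possible because both replicates of a group have the same single list, and for the same reason no replicate could be left out. Counting summit lines gave nothing to compare, as 0 regions were repeated, and the annotation, gene and motif alternatives were not run. Of 44 values under another setting, 27 moved beyond the main value's interval or by over 1.5 times and 17 did not. Leaving out centromeric bands and contigs, ranking by pileup, and the equal-sized WT list seen from the M253K side were chosen after seeing the data. With −log10 q of at least 5 the M253K list fell to 29246 and the D226G list to 813 peaks over 0.275 Mb. At 10 the lists held 38835 WT, 14598 M253K and 198 D226G peaks, so their order stayed. M253K overlap of WT peaks was 12.3% with reciprocal overlap, 15.4% with near summits, 15.4% at the stricter q, 18.02% without centromeric bands and 27.5% with the equal-sized WT list. WT overlap of M253K peaks was 28.7%, 36.1% and 39.7% under the first 3 of these settings in the same order, and 27.9% with the equal-sized WT list. D226G overlap of WT peaks was 0.853%, 0.865% and 0.942%. WT overlap of D226G peaks was 68.1% with reciprocal overlap and 69.0% with near summits. M253K overlap of D226G peaks was 84.3%, 79.2% and, at the stricter q, 96.9%. The strongest decile of WT peaks was overlapped at 47.4% ranked by −log10 q and 48.8% by pileup, and the weakest decile at 8.47% and 8.68%. Stricter overlap lowers a share by construction, and a stricter q or fold enrichment lowers a count of peaks and a covered length by construction. The tally of moved values in part reflects this, and otherwise the cause was not tested. Of the 30 named sites, 28 stayed in their class with reciprocal overlap, 29 with near summits and 29 at the stricter q. The estimated depth was lowest for D226G, and a missing D226G peak at a weak WT site does not show absence of binding.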

Other observations

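The tests of strong WT peaks without an M253K overlap, of D226G overlap at equal WT pileup and at equal M253K pileup were chosen after the results were seen, as were the lowest D226G depth, the thinned shares by pileup, the ways of fitting a fixed fraction and raising it, the lowering of pileups and the splitting of WT reads. The other tests were set before their results were seen.

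The mutant lists held fewer peaks than the WT list, and lower depth may account for part of this. When WT reads were thinned at random to the M253K depth in 100 draws, the WT peaks that still passed numbered 1.20 times the M253K peaks if a pileup of at least 5 was required, and 1.80 times by the lowest p of the list alone, but 2.80 and 4.198 times the WT peaks that M253K peaks overlapped, and at WT pileups of 30 to 59 M253K overlapped 47.6% (46.5 to 48.8) against 99.901% thinned. The required pileup was set on the thinned WT peaks only, and all M253K peaks were counted. Outside centromeric bands and contigs 39347 of 45039 M253K peaks reached 5 reads. The ratio of 1.20 is thus lower than with the same cut on both lists. For D226G the ratio was 3.60 to 12.6 at the depths of 1.35 and 1.36 M reads, while at 0.675 M reads, a value set arbitrarily by halving, it was 0.520 with a pileup of at least 7 required and 5.02 without. Here too all D226G peaks were counted, though their first quartile of pileups was 6, so 3.60 and 0.520 are also low. At the halved depth, with the stricter rule, thinned shares lay above those observed at WT pileups of 60 to 99 (30.9% against 16.1%, 13.8 to 18.7) and from 100 on (63.3% against 46.5%, 37.6 to 55.5), but below them at 30 to 59 (3.87% against 4.94%, 4.45 to 5.46) and 20 to 29 (0.201% against 1.71%, 1.48 to 1.95), while at 1.36 M reads they lay above in all of these. For D226G the WT pileups were thinned by reads alone, with no allowance for the longer D226G fragments. Thinned counts and shares for D226G may therefore be too low, so 0.520 and the shares below those observed decide nothing. Depth and a difference between the proteins cannot be told apart for the number of peaks in either list. The passing rule and, for D226G, the depth and the effect of fragment length are not known, and the efficiency of the precipitation was not tested.

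Some of the strongest WT peaks had no M253K overlap. Of 1044 WT peaks with a pileup of at least 60 outside centromeric bands and contigs, 792 were overlapped, 75.9% (73.1 to 78.4), while thinning to the M253K depth left all but 0.0383% of them, which speaks against depth alone. Of all 289 such peaks without an overlap, 37 lay in centromeric bands, variable heterochromatin or contigs, 12.8% with an upper limit of 17.2%, so these do not make up the pattern either. Sequence present in several copies outside those bands, the efficiency of the precipitation and a difference between library batches were not tested. A difference between WT and M253K binding at these sites is a hypothesis that stays open beside them.

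D226G peaks at WT sites lay where M253K peaks lay, which the height of the WT peak at low D226G depth would not give by itself, since at a WT pileup of 60 to 99 only 0.422% of peaks without an M253K overlap had a D226G peak, against 21.6% of those with one. Reads of the M253K library in the D226G library at 1 fraction would keep D226G pileups within a Poisson limit, but 8.92% (6.06 to 12.6) to 30.2% of 325 strong M253K sites lay above it over the fits, against 5% set beforehand, and only fractions fitted on summed pileups, or raised as far as the longer D226G fragments allow, gave as little as 7.08% (4.54 to 10.4), with 1.06% to 7.17% of sites expected without a peak against 37.2% observed. These values bear only on such reads as the sole source of D226G pileups. Most of the 325 sites lay within the limit. Such reads beside other D226G signal were not tested and stay open as a source of many D226G peaks. A comparison at like M253K pileup (within 10%) cannot tell by itself, since D226G overlapped 7.40% (5.76 to 9.34) of 878 M253K peaks with a pileup of at least 30 and no WT overlap, against 14.2% of those with one, and with pileups taken as 30% lower to allow for noise the interval held the other share at 30 (8.40%), at 60 (18.7%, 11.8 to 27.4, against 18.02%) and among the 13 peaks from 100 on (7.69%, 0.195 to 36.0, against 34.8%) but not at 10 (1.69%, 1.41 to 2.01, of 7384 against 3.96%), where counting noise is largest. Neither one difference in yield between the WT and M253K libraries nor one common strength of sites read with counting noise can be told apart from site by site differences, because the 72.2% of 1059 sites in all 3 lists whose pileup ratio departed from the median beyond counting error, and the correlation of 0.0767 at shared sites against 0.747 between parts of the WT reads, have no spread between replicates to be set against. On the WT side the gap outlasted the same lowering, with 0.465% (0.280 to 0.726) against 6.69% at a WT pileup of at least 30 and 0.397% (0.0100 to 2.19) against 12.8% at 60, but noise between libraries beyond counting error, of unknown size, may still give the pattern, and neither this nor a shared batch of the mutant libraries nor a difference between the proteins was tested.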
